A study of Homo sapiens with 15 samples.

How the data were processed

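Gene expression was measured with Affymetrix arrays in IMR32 cells, an established human neuroblastoma cell line that carried a doxycycline-inducible MSX1 gene. MSX1 encodes a homeodomain transcription factor. The labels place 15 arrays in 5 groups of 3: cells at t = 0, induced cells at t = 8, t = 24 and t = 48, and control cells grown without doxycycline to t = 48. No unit of time is stated in the labels. The design describes triplicate time courses, but nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. No array held doxycycline-treated cells without the construct, so an effect of doxycycline itself was not separated from that of MSX1.

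The deposited values are intensities on a linear scale, produced with MAS5 in GCOS per the submitters' processing notes, which give no version or settings. In the deposited table, the mean of each array after trimming 2 percent of the probe sets from each end was 100.01, so each array had been scaled as a whole to a target of 100. No other normalization between arrays was seen in the values. Array medians ranged from 18.1 to 22.6. A scaling of this kind leaves any difference between arrays in the spread of low signals in place. The number of arrays limits the precision of every value.

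The table held 54675 probe sets, of which 62 were array controls. The platform annotation gave exactly 1 gene symbol for 41091 probe sets and several symbols for 1801, and 11721 were not listed there. A probe set without a listed gene is unnamed here and may still have one. Symbols were matched through Entrez identifiers to the RefSeq gene table of GRCh38.p14, in which 41037 of the 41091 were found. Neither the labels nor the table name a genome build, so no coordinates are given. Some genes are not reported here.

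An offset of 5.16, the mean over arrays of the lower quartile of signal, was added before taking log2. Fold changes are on this log2(signal + offset) scale, which understates changes of genes with low signals. Probe sets were kept where the signal reached the array's median on at least 3 of the 15 arrays. For each gene, the kept probe set with the highest mean log2 value over all arrays was used, which gave 12880 genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on 5 group means, two-sided), with all 15 arrays sharing 1 estimate of the spread and Benjamini-Hochberg adjustment over the 12880 genes. The threshold was an adjusted p of 0.05. Change over the induced time course was tested with a moderated F-test on the differences of t = 8, t = 24 and t = 48 from t = 0. Figures were drawn with matplotlib 3.10.9.

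Before the data were examined, 32 gene lists with 747 entries were fixed, of which 552 were measured. For the 5 comparisons against control or t = 0, each list was tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, adjusted over the 32 lists. The test of fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. It called 16 of the 32 lists between induced and control cells at t = 48. The lists of Wnt antagonists, Notch genes and proneural factors follow genes known from this study, so they are not independent evidence of direction. Genes named in the text followed a rule fixed at the same time. It took the 12 largest rises and 12 largest falls between induced and control cells at t = 48, 8 and 8 in each comparison with t = 0, and 5 and 5 in each step between induced time points, among genes that passed the threshold and whose groups did not overlap. It also took MSX1, a few fixed genes, and up to 4 members of each list.

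The fits were tested on simulated data for the comparison of induced and control cells at t = 48, with the spread of the 12880 real genes and 200 changed genes. Noise was drawn for each gene on its own, so correlation between genes and shared array effects were left out. The real comparison called 1101 genes, so the rates below may differ there. Of the genes changed 2-fold, 75 percent were called, and of those changed 1.41-fold, 30 percent. A recovery of 80 percent of the 2-fold changes had been set as the aim beforehand and was missed. All 2-fold genes with a residual SD under the median were called (100 percent), and 51.9 percent of those with a larger one. The mean error of the log2 fold change was 0.00077, 3.67 percent of the calls were unchanged genes, and 0 genes were called when none had been changed. A gene that did not pass the threshold may therefore have changed.

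Alternatives fixed before the data were examined covered the offset, scaling between arrays, the filter, the probe set per gene, the variance model, the arrays in the fit, the replicate number as a block, the threshold, and leaving out arrays. Leaving out the pair of arrays with weak hybridisation controls, the lower quartile of signal as a covariate, and the test of whether effects differed between t = 48 and t = 24 were added after seeing the data.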

Results

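The data comprised 15 expression arrays of IMR32 neuroblastoma cells with an inducible MSX1 gene, 3 in each of 5 groups. Signals reached between 9395 and 13304 on the brightest probe set of each array. The ratio of the 3' to the 5' control probe sets of GAPDH, a sign of RNA integrity, lay between 0.96 and 1.09. That of ACTB lay between 1.18 and 1.52, with its highest values in induced t = 48 replicates 1 and 2, and read 1.27 in replicate 3 and 1.22 to 1.31 in control cells at t = 48. Hybridisation controls were weak on 2 arrays, induced t = 24 replicate 1 and induced t = 48 replicate 3, where the bioC control read 122.2 and 138.5, against 495 to 600 on the others. The 18S rRNA control read 646.5 on t = 0 replicate 3 and at most 172.9 elsewhere. At t = 48 it read 150.2 to 172.9 in induced and 76.7 to 94.9 in control cells, without overlap.

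MSX1, the induced gene, was followed first, since it checks the labels. On its brighter probe set the signal was 111 ± 13.6 (SD, n = 3) at t = 0, 161 ± 22.1 at t = 8, 165 ± 20.7 at t = 24 and 83.2 ± 14.7 at t = 48 in induced cells, and 50.7 ± 4.52 in control cells at t = 48. MSX1 was thus higher with induction at t = 48 (log2 fold change 0.65, SE 0.15, adjusted p = 0.0165) and higher at t = 24 than at t = 0 (0.55, adjusted p = 0.0299). At t = 8 the difference of 0.51 did not pass (adjusted p = 0.128). In induced cells MSX1 fell from t = 24 to t = 48 (-0.96, adjusted p = 0.0021), and its value at t = 48 against t = 0 was -0.40 and did not pass (adjusted p = 0.0777). MSX1 fell in control cells between t = 0 and t = 48 (-1.05, adjusted p = 0.00501). The call at t = 48 was lost when only the compared groups were fitted (adjusted p = 0.0587) and without the arrays with weak hybridisation controls (adjusted p = 0.0501). It was also lost without induced t = 48 replicate 1 (adjusted p = 0.0638) or 3 (0.0594), or without control replicate 1 (0.0657) or 2 (0.0551). The dimmer probe set gave -0.42 against control at t = 48 and -0.41 at t = 24 against t = 0, neither of which passed, and fell between t = 0 and t = 48 in induced cells (-0.99, adjusted p = 0.042 over all probe sets). Whether either probe set lies within the introduced construct is not known here, so neither settles how far the construct was induced.

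The comparison of induced with control cells at t = 48 asked what MSX1 induction changed at a matched time. In this comparison, rose and fell mean higher and lower in induced than in control cells. HEY1, a transcriptional repressor downstream of Notch, rose from 40.5 ± 2.64 to 871 ± 110 (SD, n = 3 each; log2 fold change 4.25, SE 0.17, adjusted p = 2.19e-08). HES1, another Notch effector, rose from 5.27 ± 3.11 to 62.8 ± 2.48 (2.75). PRG2 (4.21), LIX1 (4.02), PLEKHA6 (4.01), the collagen gene COL6A3 (3.35), the GABA receptor subunit gene GABRP (3.20) and ENPP2, which encodes autotaxin (3.02), were among the largest rises, followed by CGNL1 (2.83), SEMA5B (2.71), KIF26B (2.60) and the proteoglycan gene LUM (2.53). The largest fall was that of LMO4, a LIM-domain cofactor, from 1026 ± 21.4 to 200 ± 44.1 (-2.35). C20orf203 (-1.75), ENC1 (-1.72), the axon guidance gene SLIT3 (-1.69), TECTB (-1.62), ARHGAP28 (-1.56), SLAMF9 (-1.47), ID1 (-1.44), the chemokine receptor gene CXCR4 (-1.39), MEST (-1.39), AFF3 (-1.38) and SOX2 (-1.37) also fell; another probe set of SOX2 gave 0.11 and did not pass. MYCN, amplified in this line, read 5323 ± 432 in induced and 5483 ± 274 in control cells and did not pass (adjusted p = 0.776).

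In control cells, the mean signals of COL6A3, GABRP, HES1, LIX1, LUM and PLEKHA6 were low, between 1.2 and 14.2, and so were those of C20orf203, SLAMF9 and TECTB in induced cells, so the size of these changes depends on the offset. In total 1101 of 12880 genes differed, 678 higher and 423 lower in induced cells, and 139 and 30 of these by at least 2-fold; the 18S rRNA control and, on 2 of 3 arrays, the ACTB ratio were also higher in induced than in control cells. The share of higher genes depended on scaling: with each array centred on its median, 535 genes were higher and 631 lower. Without the arrays with weak hybridisation controls 783 genes differed. Leaving out 1 array gave 709 genes without induced t = 48 replicate 2 and 625 without replicate 3, and 674, 659 and 707 without control replicates 1, 2 and 3.

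**Figure D1:**
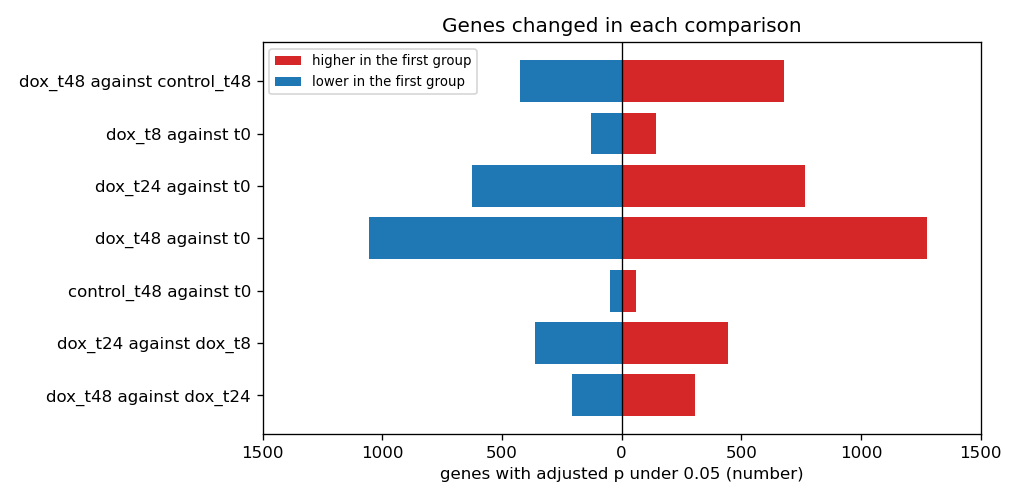
Bars show the number of genes past the threshold in each comparison (horizontal axis, genes), to the right for genes higher in the first-named group and to the left for genes lower in it; dox marks induced cells. The comparison of induced t = 48 with t = 0 has 1275 higher and 1056 lower genes, and control t = 48 with t = 0 has 62 and 47.

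Among the gene lists, the G2 and mitosis genes fell together at t = 48. Of 32 measured members, 22 fell and 0 rose, or 25 and 0 when adjusted over the list alone, with CDC20 (-0.71), AURKB (-0.65), PLK1 (-0.60) and CDCA8 (-0.60) among them. The list median was -0.38 (camera adjusted p = 5.05e-17; adjusted p = 0.066 with an estimated correlation), and 15 members fell without the arrays with weak hybridisation controls. Of 31 G1-S and DNA replication genes, 9 fell and 0 rose (18 fell adjusted over the list alone), MCM10 (-0.47) and MCM5 (-0.39) among them (camera adjusted p = 2.25e-10; adjusted p = 0.0513 with an estimated correlation). CDKN1C, which encodes a cyclin-dependent kinase inhibitor, rose (1.49) as the 1 cell cycle inhibitor of 12 to pass. Cholesterol synthesis genes fell as a list (camera adjusted p = 8.78e-06; adjusted p = 0.0453 with an estimated correlation), with 3 of 16 members past the threshold, NSDHL (-0.50), SC5D (-0.44) and STARD4 (-0.43), and 10 adjusted over the list alone.

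Of 32 extracellular matrix and adhesion genes, 10 rose and 0 fell (12 and 1 adjusted over the list alone). COL6A3, LUM, the protease inhibitor gene TIMP3 (2.13) and the integrin gene ITGA6 (1.69) led them (camera adjusted p = 0.00226; adjusted p = 0.306 with an estimated correlation). Fibroblast markers, of which 4 of the 9 measured are also in that list, had 3 members higher, LUM, COL3A1 (1.06) and PDGFRA (0.40), while their median was -0.04 and their mean 0.39 (camera adjusted p = 0.119); adjusted over the list alone 4 rose and 0 fell. Of 20 mesenchymal genes, CDH11 (1.76), FN1 (0.97) and SNAI2 (0.85) rose and 0 fell, but 3 rose and 3 fell adjusted over the list alone. The median of that list was -0.05 and the mean 0.07; it did not pass camera (adjusted p = 0.878) and passed fry (adjusted p = 3.3e-05). Of 27 neuronal differentiation genes, 7 rose and 0 fell (11 and 1 adjusted over the list alone), including STMN2 (1.67), PRPH (0.79) and DCX (0.77), with camera adjusted p = 0.0115 and adjusted p = 0.122 with an estimated correlation; without the arrays with weak hybridisation controls 3 rose. The granule genes CHGB (1.21), SCG3 (0.97) and CHGA (0.90) and the dopamine-synthesis gene DDC (0.74) rose among 15 catecholamine and chromaffin granule genes, of which 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.174, not passed).

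Of 24 Notch genes, 4 rose and 1 fell (7 and 1 adjusted over the list alone). HEY1, HES1, MAML3 (0.78) and MAML2 (0.67) were the ones that rose; the second-brightest probe set of MAML3 gave -0.15. This list and those of Wnt antagonists and proneural factors were chosen from the study's own subject and are not independent evidence. The Notch list did not pass camera (adjusted p = 0.057). SFRP1, a secreted Wnt antagonist, rose from 229 ± 16.8 to 505 ± 38.3 (1.12, adjusted p = 0.000172), as 1 of 6 Wnt antagonists; over the list alone 1 rose and 3 fell. DKK1 (-0.44, adjusted p = 0.16), DKK3 (0.05), DLK1 (0.44) and NOTCH3 (-0.34) did not pass. WNT5A was the 1 of 19 Wnt ligands and receptors to rise (1.35). Of 13 proneural genes, MYT1 (0.97) rose, and NHLH2 (-0.77) and EBF3 (-0.43) fell (2 and 3 adjusted over the list alone). Adrenergic regulators moved both ways, 5 up and 3 down of 19 (6 and 4 adjusted over the list alone), with ALK (0.99) and PHOX2A (0.70) higher and ISL1 (-1.20) and EYA1 (-0.83) lower. Among 20 BMP and TGF-beta genes 2 rose and 5 fell (4 and 7 adjusted over the list alone), with BAMBI (0.66) higher and ID1, TGFB2 (-0.83) and ID4 (-0.68) lower. Of 10 neural crest genes 3 rose, among them SOX9 (0.85) and EDNRB (0.72), and 2 fell, among them SOX2.

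Of 28 hypoxia and glycolysis genes 4 rose, among them NDRG1 (1.91), ADM (1.28) and VEGFA (1.14); another probe set of VEGFA gave -0.02 and did not pass. Adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.235, not passed). The lists of Notch, catecholamine, hypoxia and fibroblast genes, which did not pass camera, passed fry, with adjusted p of 0.000393, 0.00508, 0.000163 and 0.00238. Those of heat shock (fry adjusted p = 0.00249), cell cycle inhibitor (0.00362), BMP and TGF-beta (0.0246), immediate early (0.041) and distal-less and Msx family genes (0.0466) did the same. The median of the heat shock list was -0.10. DLX5 (0.67) and LHX8 (0.69) were the 2 of 14 distal-less and Msx family genes and cofactors that rose. Apoptosis regulators, MYC and ribosome biogenesis genes, heat shock genes and housekeeping genes had 0 members past the limma threshold. The mitochondrial translation list passed at the preset correlation (camera adjusted p = 0.0187; adjusted p = 0.442 with an estimated correlation), with TFAM (-0.31) as the 1 member past the threshold. Of the markers of other cell types, 0 of 4 epithelial and 0 of 4 blood and endothelial genes passed. L1CAM (0.53) was the 1 of 2 Schwann cell markers to pass. It is also in the neuronal differentiation list, so it does not point to Schwann cells alone.

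**Figure D2:**
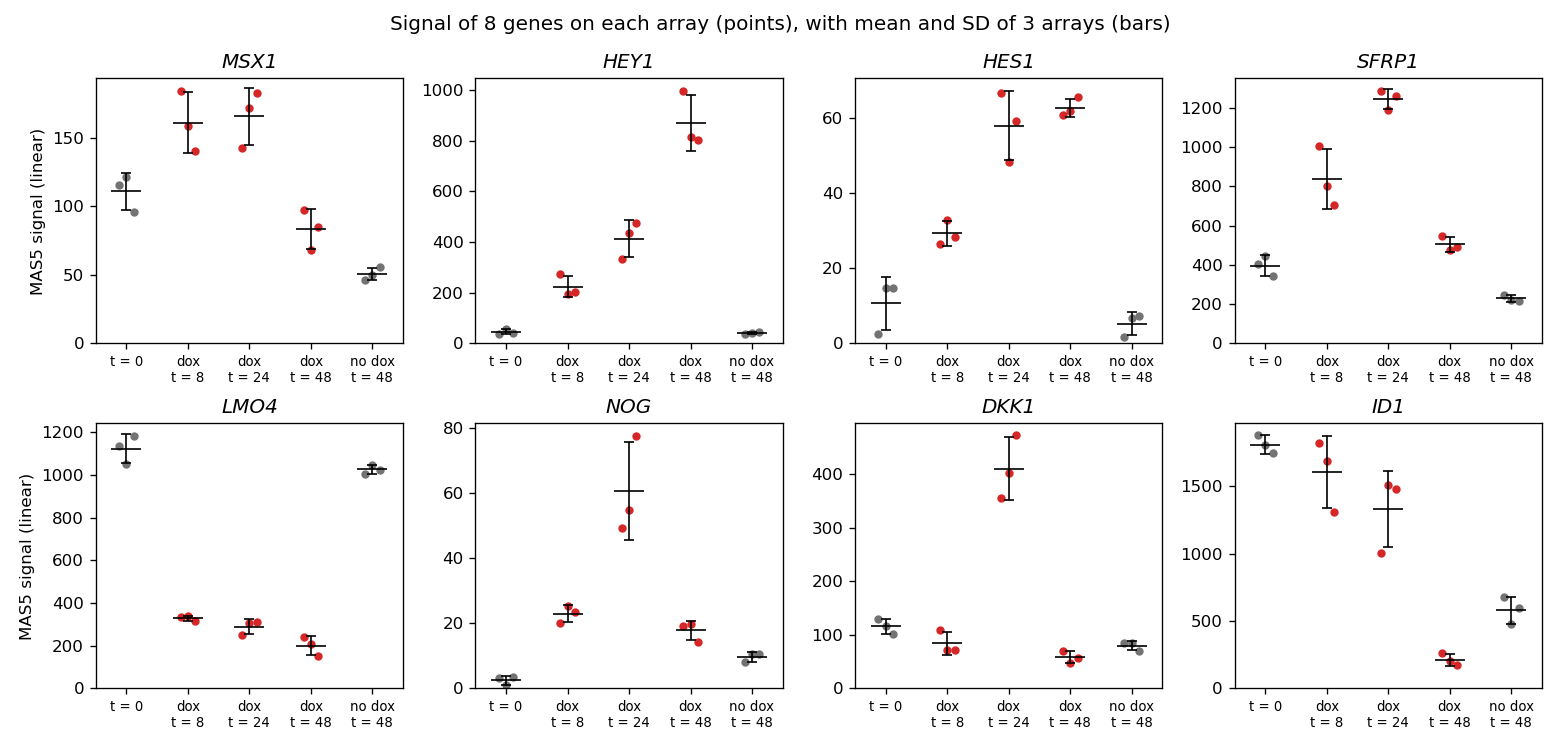
Each panel shows 1 gene; the vertical axis is the linear MAS5 signal from 0 and the horizontal axis the group, with red points for arrays of induced cells, grey for arrays without doxycycline, and bars for the mean and SD of 3 arrays. HEY1 reaches 871 on average in induced cells at t = 48 against 40.5 in controls, DKK1 peaks at 410 at t = 24, and ID1 averages 212 in induced and 581 in control cells at t = 48 against 1808 at t = 0.

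The time course asked how early changes appeared in induced cells. No control cells were measured at t = 8, so the differences there from t = 0 hold time in culture as well as induction. By t = 8, HEY1 had risen (log2 fold change 2.16 against t = 0, adjusted p = 3.49e-05), as had PLEKHA6 (2.23), P3H2 (2.18), the apelin receptor gene APLNR (1.94), NOG, which encodes a BMP antagonist (1.89), CGNL1 (1.82), TIMP3 (1.77), SMTNL2 (1.71) and SFRP1 (1.06). LMO4 (-1.75), CXCR4 (-1.67), the proneural gene NEUROG2 (-1.62), ESRRG (-1.29), PAG1 (-1.28), ADRA2A (-1.26) and PCDH19 (-1.20) had fallen. SPDEF fell on its brightest probe set (-1.50), while its other 3 probe sets gave 1.02, 0.02 and 0.43 and did not pass, so its direction is open. CDKN1C (1.51) and GADD45G (0.98) rose, and 0 of 32 G2 and mitosis genes passed. Of 270 changed genes, 142 were higher and 128 lower; the count was 173 without induced t = 8 replicate 1, and 174 and 179 without t = 0 replicates 1 and 3. The lists of proneural factors (lower), of heat shock, neural crest and distal-less and Msx family genes (higher) passed camera at the preset correlation, and 0 of 32 lists passed with an estimated correlation (lowest adjusted p = 0.144).

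At t = 24, LIX1 (3.92), GABRP (3.74), P3H2 (3.56), LUM (3.48), NOG (3.09), HEY1 (3.03), COL6A3 (3.02) and CGNL1 (2.69) were the largest rises against t = 0. LMO4 (-1.94), ENC1 (-1.85), PAG1 (-1.71), CFAP73 (-1.63), CXCR4 (-1.47), PLEKHF1 (-1.40), ADGRG1 (-1.39) and CCDC88B (-1.33) were the largest falls. Both DKK1, from 116 ± 13.8 to 410 ± 59.3 (1.77, adjusted p = 4.44e-05), and SFRP1, from 397 ± 52.97 to 1243 ± 51.8 (1.64), rose, as did DKK3 (0.45), while FRZB fell (-0.47). In total 767 genes were higher and 627 lower; with arrays centred on the median, 601 and 1037. Without the arrays with weak hybridisation controls 953 genes changed; without induced t = 24 replicate 1 alone 897, and without t = 0 replicate 3 919.

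More lists passed at t = 24 than in any other comparison, 15 of 32 at the preset and 9 with an estimated correlation. Of the G2 and mitosis genes 21 of 32 fell and 0 rose (adjusted p = 0.0448 with an estimated correlation), and of the G1-S genes 16 of 31 fell (list adjusted p = 0.0318 with an estimated correlation). Extracellular matrix genes rose, 13 of 32 (list adjusted p = 0.0465 with an estimated correlation), with COL1A1 (1.38) and ITGA6 (2.17); another probe set of COL1A1 gave -0.13 and did not pass. Beside them 4 of 9 fibroblast markers rose, LUM, COL1A1, COL3A1 (1.05) and PDGFRA (0.68), while DCN, ACTA2, TAGLN, THY1 and PDGFRB did not pass (list adjusted p = 0.0449 with an estimated correlation). Of the other cell-type markers, 1 of 4 blood and endothelial and 1 of 2 Schwann cell genes rose, and 0 of 4 epithelial genes passed. Heat shock genes fell, 8 of 15 (list adjusted p = 0.0144 with an estimated correlation), among them DNAJB1 (-0.58) and HSPH1 (-0.51); this list also fell in control cells between t = 0 and t = 48. Among stress response genes 8 of 24 fell, such as PHGDH (-0.57), and 1 rose, DDIT4 (2.02), for a list adjusted p = 0.0318 with an estimated correlation. Distal-less and Msx family genes rose, 5 of 14 (list adjusted p = 0.0465 with an estimated correlation), with MSX2 (1.83) and DLX5 (1.31), and mesenchymal genes rose, 4 of 20 (list adjusted p = 0.0318 with an estimated correlation), with CDH11 (1.93). Ribosome biogenesis genes fell, 5 of 21 (list adjusted p = 0.0465 with an estimated correlation), among them RRP9 (-0.60). The BMP list rose at the preset correlation, 5 of 20 members higher and 1 lower (camera adjusted p = 0.0484; adjusted p = 0.086 with an estimated correlation). Housekeeping genes had 0 of 14 past the threshold, with a median of -0.18 (camera adjusted p = 0.0368; adjusted p = 0.359 with an estimated correlation).

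At t = 48 against t = 0, ENPP2 (4.61), HEY1 (4.10), LIX1 (4.05), PRG2 (3.96) and PLEKHA6 (3.86) were highest, and ID1 (-3.08), LMO4 (-2.48), SLIT3 (-2.14), LINC02593 (-2.06), ID3 (-2.01), CKM (-1.98) and C11orf96 (-1.94) fell most, with 1275 genes higher and 1056 lower (1020 and 1627 with arrays centred on the median); without induced t = 48 replicate 3 the count was 1505. G2 and mitosis genes were lower in 25 of 32 cases (camera adjusted p = 1.2e-13; adjusted p = 0.125 with an estimated correlation), and DKK1 was below its t = 0 level (-0.95, adjusted p = 0.0034). Of 20 mesenchymal genes 2 were higher and 6 lower (3 and 6 adjusted over the list alone), with CDH11 (1.74) higher and SNAI1 (-1.12) lower; the median was -0.18 and the list did not pass camera (adjusted p = 0.532). Over the induced time course 2591 genes changed by the F-test, with the largest difference from t = 0 at t = 8 for 209, at t = 24 for 804 and at t = 48 for 1578.

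From t = 8 to t = 24, 444 genes rose and 364 fell, with LUM (3.28), GABRP (2.76), COL6A3 (2.55), LIX1 (2.42) and DKK1 (2.24) rising most and HAPLN4 (-1.50), ARID5A (-1.36), MAPK8IP1 (-1.34) and CHST1 (-1.10) among the largest falls. With arrays centred on the median 342 rose and 679 fell. The count of 808 fell to 398, 468 and 534 without induced t = 8 replicates 1, 2 and 3, and to 402 and 489 without induced t = 24 replicates 1 and 3. From t = 24 to t = 48, 306 rose and 208 fell. ENPP2 (2.35), PRG2 (2.13), STMN2 (1.96), ADAMTS8 (1.92) and GRK5 (1.86) rose, and DKK1 (-2.72), ID1 (-2.62), the tetraspanin gene CD9 (-2.37), ID3 (-2.28) and LINC02593 (-2.00) fell. Without the arrays with weak hybridisation controls, 490 genes changed in the first step and 337 in the second.

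Control cells gave the background of the time course. Between t = 0 and t = 48 without doxycycline, TNR (2.04), ENPP2 (1.59), RGS4 (1.53), SLC44A5 (1.40), CHRNA1 (1.19), CDH6 (1.09; another probe set gave -0.18 and did not pass), MFNG (1.09) and CNTN3 (1.07) rose, and ID1 (-1.64), TGFA (-1.60), ID3 (-1.56), SAMD11 (-1.16), CHST8 (-1.16), SNAI2 (-1.09), MSX1 and SCN3B (-0.97) fell. SFRP1 also fell (-0.77, adjusted p = 0.0153), and HEY1 did not pass (-0.15, adjusted p = 0.803). Only 109 genes changed, 62 up and 47 down, against 1442 at an unadjusted p under 0.05; the count was 51 and 33 without control replicates 2 and 3 and 44, 58 and 70 without t = 0 replicates 1, 2 and 3, and with only the compared groups in the fit limma called 0. Of 32 lists, 3 passed camera at the preset correlation and the heat shock list, which fell, also with an estimated one (adjusted p = 0.0398). Its median was -0.17, with DNAJB1 (-0.45) lower as 1 of 15 members, or 5 adjusted over the list alone. The median of the G2 and mitosis genes was -0.04, and 0 of 32 passed.

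**Figure D3:**
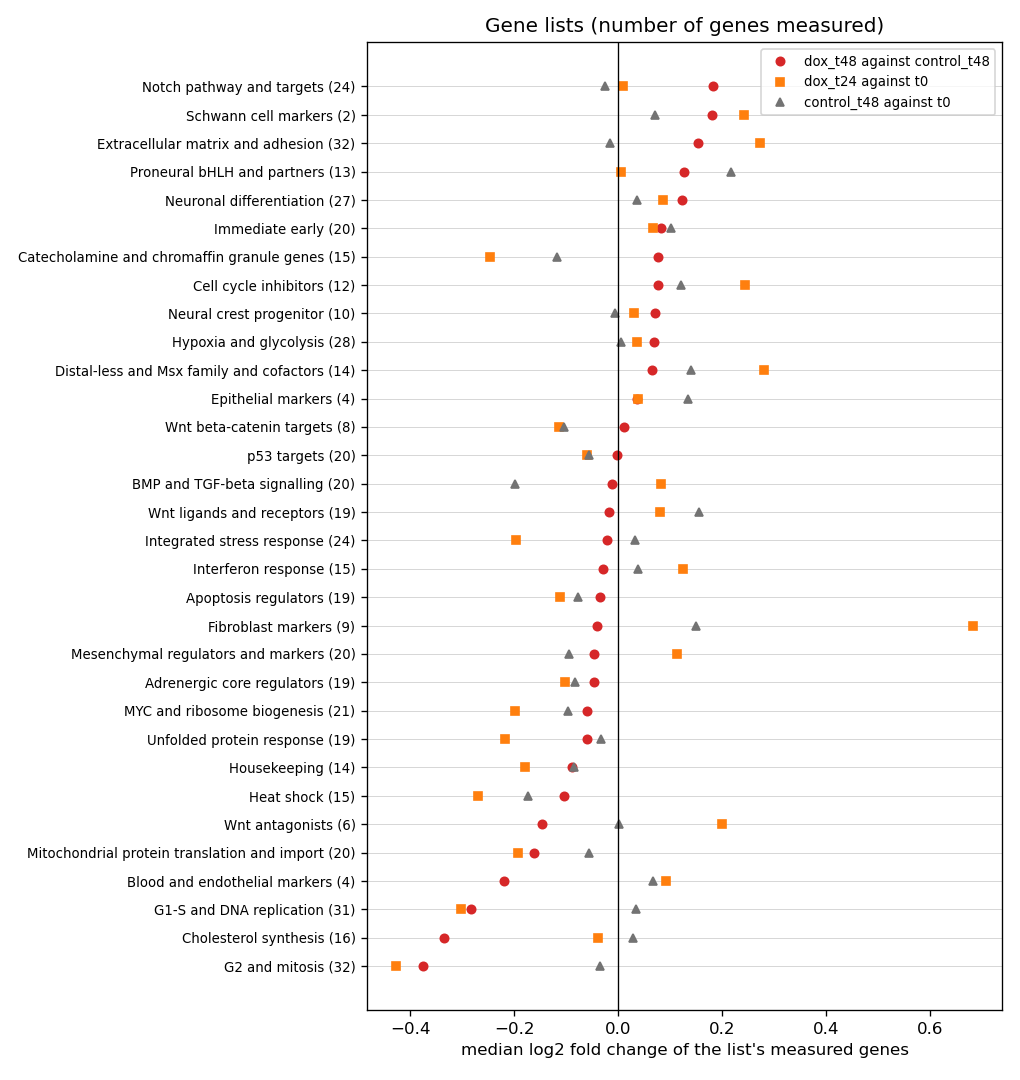
Points show the median log2 fold change (horizontal axis) of each gene list (vertical axis, with the number of genes measured) for induced against control cells at t = 48 (red circles), induced t = 24 against t = 0 (orange squares) and control t = 48 against t = 0 (grey triangles). The G2 and mitosis list lies at -0.38 and -0.43 in the comparisons with induced cells and at -0.04 in the controls.

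The effects at t = 48 against control and at t = 24 against t = 0 rest on separate arrays, though perhaps on the same 3 time courses. Their calls are not independent, since for each gene they share an estimate of the spread from all arrays. Each induced group also holds an array with weak hybridisation controls, and the residuals of these arrays correlated at 0.37. Of the 1101 genes called in the first, 1024 (93.0 percent) had the same sign in the second. Without the arrays with weak hybridisation controls the share was 92.7 percent. With all arrays, 370 genes were higher in both comparisons, against 40.4 for independent lists, and 210 were lower, against 20.6. Genes with a small shared spread are more readily called in both, so these expected counts may be too low. The correlation of the fold changes was 0.61 across genes, which are not independent replicates. Calls in opposite directions were made for 7 genes, among them CD9, GRK5 and SULF2, the last chosen after its values were seen. With the effect at t = 8, 782 of the 1101 genes (71.0 percent) shared the sign, and 105 were higher in both, against 7.47 for independent lists. The shared spread limits this expected count in the same way.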

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

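All tests of explanations in this part were chosen after the results they concern were seen, except the counts of other splits. The difference between induced and control cells at t = 48 and the change from t = 0 to t = 24 in induced cells were unlike for 40 of 12880 genes, 16 with a higher and 24 with a lower value at t = 48, in a limma contrast of the difference that was added after seeing the data; 1038 genes had an unadjusted p under 0.05. No control cells were measured at t = 24, so the value there holds time in culture as well as induction; in control cells NOG rose by 0.97 between t = 0 and t = 48. Among the genes named by size or fixed beforehand, NOG (difference -2.47, adjusted p = 0.000672), DKK1 (-2.21, adjusted p = 0.00186), CD9 (-2.01, adjusted p = 0.000153), ARHGAP28 (-1.26, adjusted p = 0.0285) and C11orf96 (-1.09, adjusted p = 0.00316) had lower values at t = 48. PRG2 (2.37, adjusted p = 0.000323) and GRK5 (1.62, adjusted p = 0.0247) had higher ones. CD9 passed in both comparisons with opposite signs, 0.83 at t = 24 and -1.18 at t = 48, and so did GRK5, -0.72 and 0.91. Probe sets without a single gene symbol were not used in the comparisons above: of 5640 kept, 85 were higher and 13 lower in induced than in control cells at t = 48, against 2 and 3 in control cells between t = 0 and t = 48.

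The fall of the G2 and mitosis genes in induced cells at t = 48 was weighed against technical explanations. After quantile normalization the list median was still -0.35, which argues against scaling between arrays. The comparison with control cells at t = 48 is matched in time, so time in culture bears on the fall from t = 0. Against t = 0 the median was -0.41 in induced and -0.036 in control cells at t = 48. These values argue against time in culture alone for the fall from t = 0. Without the arrays with weak hybridisation controls the list median between induced and control cells at t = 48 was -0.32. Doxycycline itself cannot be told apart from MSX1, since 0 arrays held treated cells without the construct; a lower share of dividing cells after induction is therefore a hypothesis with that explanation open.

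The 2 arrays with weak hybridisation controls had residuals that correlated at 0.37, the highest of 60 pairs of arrays with different numbers in different groups. Without both, 783 genes differed between induced and control cells at t = 48, among them 698 of the 1101 called with all arrays. Only induced t = 48 replicate 3 is in this comparison, and without it alone 625 genes differed, 589 of them among the 1101. In each case most of the 1101 calls stayed, which argues against these arrays as the source of most calls.

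The BMP target genes ID1, ID2, ID3, ID4, SMAD6 and SMAD7 fell from t = 24 to t = 48 in induced cells, with a median of -1.19 (chosen after their values were seen), and had a median of -0.62 in control cells between t = 0 and t = 48. Between induced and control cells at t = 48 all 6 had negative values, and ID1 (-1.44, adjusted p = 0.000543), ID4 (-0.68, adjusted p = 0.0301) and SMAD6 (-0.42, adjusted p = 0.0351) passed. The genes that passed were picked by this same comparison, so they do not weigh time in culture for the set. For the 6 as a set the median there was -0.43, with a standard error of 0.249 taken across the genes. That error measures how unlike the 6 genes were and not the spread between arrays. It therefore cannot decide on time in culture alone for the set. The comparison is itself matched in time, so time in culture bears on the falls from t = 0 and from t = 24. The rise of NOG may contribute, but the median of the 6 genes was 0.085 at t = 24 against t = 0, where NOG was highest. There ID2 was higher (0.61, limma adjusted p = 0.000359). ID1 (-0.46), ID3 (0.28), ID4 (-0.23), SMAD6 (-0.07) and SMAD7 (0.25) did not pass. The 6 genes moved both ways there, which leaves the question open.

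The 6 arrays of each comparison can be divided into groups of 3 in 10 ways, the real one included, too few for a share under 0.05. In a mixed division, any difference between the groups counts as spread and lowers the number of genes called. The counts of the other divisions are therefore no measure of false calls. The real division was the 1 with the most genes in each. It gave 1101 genes for induced against control at t = 48 (highest other 1), 270 at t = 8 (1), 1394 at t = 24 (1) and 2331 at t = 48 against t = 0 (1). It gave 109 for control cells (3), 808 for t = 24 against t = 8 (0) and 514 for t = 48 against t = 24 (2). For the F-test, 1 of 100 divisions of the 12 arrays, the real one, gave 2591 genes, and the highest other gave 1384. This share of 0.01 is the lowest that 100 divisions can give. It argues against chance as the source of that count without excluding it.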

How the results depend on the processing

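Leaving out the arrays with weak hybridisation controls and the lower quartile of signal as a covariate were chosen after seeing the data. Below, the order of counts is induced against control at t = 48, then t = 8, t = 24 and t = 48 against t = 0, control cells, the steps to t = 24 and to t = 48, and the F-test, unless stated. The offsets, quantile normalization, median centring, the stricter filter, all probe sets, the variance trend with a robust fit, and the covariate left each of these counts within 1.5 times its value and MSX1 past the threshold at t = 48. With no filter on low signals, which adds genes to the test, there were 684 genes for induced against control cells, 926 at t = 24, 56 in control cells and 404 in the step to t = 24. With the second-brightest probe set the counts were 637, 129, 824, 1471, 33, 376, 300 and 1619. At a threshold of 0.01 they were 441, 131, 597, 1025, 41, 269, 282 and 1252, and the sign was shared by 95.5 percent of genes. With a 2-fold minimum they were 169, 52, 195, 289, 16, 60, 109 and 343. With only the groups compared in the fit, and fewer arrays to estimate the spread, limma gave 617, 52, 475, 1117, 0, 89 and 261 for the first 7; 1442 genes of the control comparison had an unadjusted p under 0.05 with all arrays. Under each of these last 3 settings MSX1 kept its 0.65 and did not pass. Without the arrays with weak hybridisation controls the steps gave 490 and 337 genes, and MSX1 0.63, which did not pass. Leaving out 1 array or 1 replicate number gave 202 to 816 genes, 37 to 194, 280 to 1109, 446 to 1968, 0 to 88, 56 to 567, 103 to 461 and 452 to 2506, a shared sign in 90.1 to 95.5 percent, and MSX1 at 0.48 to 0.78. Over its alternatives the adjusted p of MSX1 ran from 0.00798 to 0.455.

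With the second-brightest probe set the sign turned for MSX1 at t = 48 against control (-0.42) and at t = 24 (-0.41). It also turned against control for ETS1 (-0.022), JUN (0.37) and MAML3 (-0.15), at t = 8 for SPDEF (0.020) and ETS1 (-0.029), and at t = 24 for LRP6 (-0.14). At t = 48 against t = 0 it turned for ATF6 (-0.72), BCL2L11 (-0.0089), ETS1 (-0.20), JUN (0.20) and PDGFRA (-0.18); the cause was not tested. Of 12754 values of named genes under the alternatives, not counting those of MSX1 at t = 48 against control, 10783 stayed on the same side of the threshold. Another 1940 no longer passed and 19 passed in addition. For 12 the sign changed and the value passed in the main fit or under the alternative. Sign changes that passed in neither are among the 10783. With the replicate number as a block, 899 genes differed between induced and control cells. No pairing by number was seen in the residuals, where 4 of 15 arrays correlated best with an array of their own number. In no comparison did all same-number correlations exceed 0.1, the value set beforehand for pairing. Weak residual correlation cannot show whether the numbers mark shared time courses. Low signals limit what can be seen of genes near the array background.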

Other observations

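GCH1, which encodes an enzyme of tetrahydrobiopterin synthesis, was lower in induced cells at t = 24 than at t = 0 (-0.92, adjusted p = 0.0123) and higher at t = 48 than at t = 0 (0.81, adjusted p = 0.0162). In control cells its difference between t = 0 and t = 48 was 0.735 and did not pass (adjusted p = 0.148), and induced and control cells at t = 48 differed by 0.08 and did not pass (adjusted p = 0.849). Of 15 catecholamine and chromaffin granule genes, 1 rose and 4 fell in induced cells at t = 24 against t = 0 (3 and 6 adjusted over the list alone), a time at which no control cells were measured. SLC6A2, the noradrenaline transporter gene, rose (0.98), and GAL (-0.75) and NPY (-0.70) were among the falls; the list did not pass camera (adjusted p = 0.142).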
